A study of Mus musculus with 24 samples.

How the data were processed

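RNA was sequenced from cultures of neurons and astrocytes of mice whose Eif2ak3 (Perk) gene carries loxP sites. Per the labels, Perk KO cells had received a lentivirus with active Cre recombinase, which cuts out the part of a gene between loxP sites, and WT cells an inactive form of it. Tunicamycin (TM), an inhibitor of N-linked glycosylation that makes unfolded proteins accumulate in the ER, was given at 5 µg/mL for 24 hours at day in vitro 14, and controls received the solvent DMSO, per the labels' protocols. Libraries were made from total RNA with the NEBNext Ultra RNA kit, amplified by PCR and sequenced as paired-end reads on a NovaSeq instrument. The 24 libraries form 8 groups of 3. The titles call the 3 libraries biological replicates without saying whether they came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

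Per the submitters' processing notes, reads were filtered with fastp, aligned with HISAT2 to GRCm38.p6 and counted per gene with featureCounts. Versions and the annotation release were not given in the sources used here. The authors deposited 8 tables, 1 for each comparison of 2 groups, which hold raw read counts per gene for its 6 libraries, per the file headers. The deposited tables also hold the authors' log2 fold change, p-value and adjusted p-value of each gene, from DESeq2 per the submitters' processing notes, the gene length, and normalized and FPKM columns that were not used here. Each library is in 2 tables, and 0 counts differed between them. A gene listed in only 1 of the tables had at most 1 count there. The tables together list 32728 genes, and 0 entries name no gene. Gene identifiers, symbols, coordinates in GRCm38 and biotypes are those of the deposited tables.

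Total counts per library ranged from 16 to 25.9 M. Reads amplified by PCR without molecular identifiers are not independent molecules, so binomial intervals cover counting error only. Replicates of a group differed by more than sampling noise, with a chi-square statistic per gene of 7.06 to 70.6, and none was treated as a copy of another. The library kit does not mark the strand, so reads of overlapping and antisense genes cannot be told apart. Counts of genes with near-identical copies are uncertain, among the genes named here those of ribosomal proteins, Hist1h1d, the Gbp genes and Ifit3.

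Raw counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalisation and the quasi-likelihood F test. Each comparison of 2 groups was fitted on its own 6 libraries, the genotype by TM and cell type by TM interactions on 12, and the 3-way interaction on all 24. Genes with a mean of at least 10 counts over the libraries of a fit were tested, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error of a log2 fold change is its size divided by the square root of F. Levels in CPM were TMM-normalised over the 12 libraries of a cell type, so that levels are not compared between neurons and astrocytes. Residual degrees of freedom were 4, 8 and 16.

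Gene lists, 33 in all, were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with the estimated correlation as a second test, and adjusted over the lists of a comparison. Members were counted by their adjusted p over all genes tested and again adjusted over the list alone. Groups, tests, filters, gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. Named genes are 13 fixed ones (Eif2ak3, Atf4, Ddit3, Trib3, Chac1, Asns, Hspa5, Hsp90b1, Xbp1, Dnajb9, Herpud1, Sdf2l1 and Eif2b5), the 8 largest rises and 8 largest falls of each comparison among called protein-coding genes with a mean of at least 100 counts and, between 2 groups, no overlap of the libraries, and up to 4 members of each described list with the smallest p. Members of a list that moved against the rest are named where 5 or fewer did, and were chosen after their values were seen. Some genes that the rule for named genes takes are not reported. Which of the 33 lists to describe for each comparison was chosen after their values were seen.

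The alternatives were no filter on low counts, DESeq2's size factors in edgeR, DESeq2 1.42.0, the replicate number as a block, and each library left out in turn, which leaves arms of 2 libraries. A correction for the GC content of transcripts was added after the data were seen: an offset per gene and library from the trend of log2 CPM over 20 bins of GC content, with longest transcripts of the GENCODE annotation of GRCm38, which gave 99.8% of tested genes a value. Replicate numbers are those in the titles, which do not say that a number marks a shared culture, litter or day. Whether they pair libraries was checked by the correlation, across genes, of deviations from group means. In astrocytes it was 0.26 to 0.60 for all same-numbered pairs, and in neurons 0.15 to 0.33 between control WT and control Perk KO and 0.18 to 0.45 between TM-treated WT and TM-treated Perk KO. Each of these was over 0.1, so the numbers were taken to pair those groups. They were not taken to do so between TM and control in neurons.

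The fits were tested on simulated counts with 200 changed genes. In the simulation of TM in WT neurons (15546 genes), 17.2%, 66.7% and 91.0% of genes changed 1.5-fold, 2-fold and 4-fold were called, all with the right sign, and 9.2% of the calls were false. For the effect of Perk KO in control astrocytes (15196 genes) the shares were 23.8%, 56.7% and 86.7%, and for the neuronal genotype by TM interaction (15939 genes) 4.23%, 36.4% and 74.6%. In the 3-way interaction (15924 genes) they were 0%, 13.4% and 56.7%. On simulated counts with a GC trend between control WT and control Perk KO neurons (15757 genes) and no changed gene, 3998 genes were called without and 0 with the correction.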

Results

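Gene expression was measured by RNA sequencing in 24 libraries of cultured mouse neurons and astrocytes, with 3 libraries in each of 8 groups. The groups combined cell type, genotype (WT or Perk KO) and treatment (control or TM). Perk is the study's name for Eif2ak3, which encodes a kinase of the ER membrane that phosphorylates the translation factor eIF2 when unfolded proteins accumulate. Per library, genes received 20.5, 20.3 and 16 M counts in control WT neurons and 18.2, 18.5 and 18.7 M in TM-treated WT neurons. The totals were 22.5, 17.9 and 18.2 M in control Perk KO neurons and 25.9, 17.2 and 19.5 M in TM-treated ones. In astrocytes they were 20.2, 18.2 and 18.4 M (WT control), 18.6, 17.7 and 19.8 M (WT TM), 17.9, 17.2 and 18.0 M (Perk KO control) and 18.2, 17.2 and 17.2 M (Perk KO TM). Levels are given as CPM (counts scaled to the library total), normalised within each cell type, as mean ± SD (n = 3). Changes are log2 fold changes ± standard error between 3 and 3 libraries, with adjusted p-values from edgeR's quasi-likelihood test.

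The targeted gene, Eif2ak3 (ENSMUSG00000031668, chromosome 6, positions 70844515 to 70905245 in GRCm38), was measured in every group before any comparison. Its level was 34.7 ± 2.74 CPM in control WT neurons and 5.24 ± 0.333 CPM in control Perk KO neurons, so that 15.1% of the WT level was left. With TM the levels were 141 ± 7.07 CPM in WT and 12.4 ± 3.23 CPM in Perk KO neurons, which left 8.84%. In astrocytes, controls held 26.2 ± 1.63 CPM (WT) and 6.83 ± 0.869 CPM (Perk KO), which left 26%. TM-treated astrocytes held 88.3 ± 15.3 CPM (WT) and 13.7 ± 2.17 CPM (Perk KO), which left 15.5%. The log2 difference between Perk KO and WT was -2.73 ± 0.12 in control neurons (adjusted p = 4.29e-05), -3.44 ± 0.18 in TM-treated neurons (1.86e-05), -1.94 ± 0.14 in control astrocytes (0.00261) and -2.66 ± 0.17 in TM-treated astrocytes (8.58e-06). Each library labelled Perk KO lay below each WT library of its cell type and treatment. The counts cover the whole gene and cannot resolve the exons removed by Cre.

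**Figure D1:**
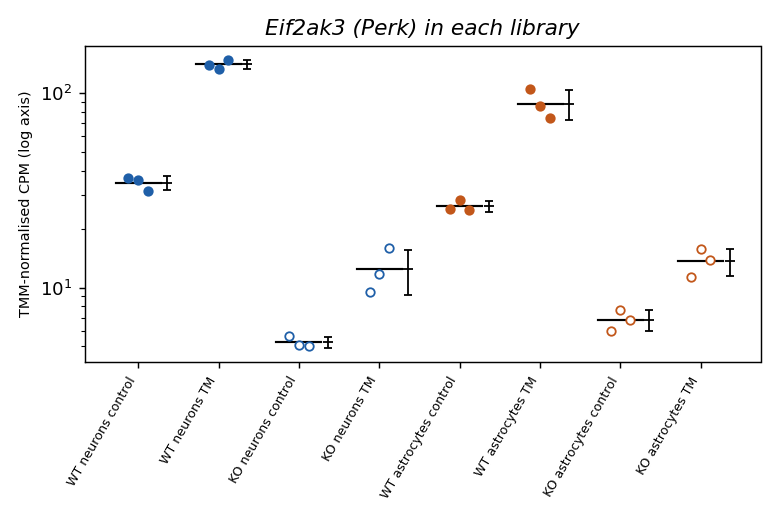
Eif2ak3 level in TMM-normalised CPM (vertical log axis) in each of the 24 libraries (points) of the 8 groups (horizontal axis), with the mean as a line and the SD as an error bar beside it (n = 3). Perk KO libraries lay below WT libraries in both cell types, at 15.1% of the WT mean in control neurons and 26% in control astrocytes.

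Another 12 genes had been fixed for naming beforehand because they report the arms of the unfolded protein response or eIF2 signalling. In GRCm38 these were Atf4 (ENSMUSG00000042406, chromosome 15, positions 80255184 to 80257541), Ddit3 (ENSMUSG00000025408, chromosome 10, positions 127290774 to 127296288), Trib3 (ENSMUSG00000032715, chromosome 2, positions 152337422 to 152344032), Chac1 (ENSMUSG00000027313, chromosome 2, positions 119351229 to 119354381), Asns (ENSMUSG00000029752, chromosome 6, positions 7675169 to 7693254) and Hspa5 (ENSMUSG00000026864, chromosome 2, positions 34771970 to 34777547). The others were Hsp90b1 (ENSMUSG00000020048, chromosome 10, positions 86690209 to 86705509), Xbp1 (ENSMUSG00000020484, chromosome 11, positions 5520659 to 5525893), Dnajb9 (ENSMUSG00000014905, chromosome 12, positions 44205559 to 44210326), Herpud1 (ENSMUSG00000031770, chromosome 8, positions 94386438 to 94395377), Sdf2l1 (ENSMUSG00000022769, chromosome 16, positions 17130140 to 17132383) and Eif2b5 (ENSMUSG00000003235, chromosome 16, positions 20498817 to 20509955).

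The response of neurons with intact Perk to ER stress was given by TM against control in WT neurons. TM raised Hspa5, which encodes BiP, the main chaperone of the ER lumen, from 531 ± 10.8 to 10715 ± 569 CPM, a 19.7-fold rise (log2 change 4.30 ± 0.10). Ddit3, which encodes the stress-induced transcription factor CHOP, rose 21.9-fold from 45.9 ± 2.06 to 1031 ± 97.7 CPM. Ranks by size, here and below, cover called protein-coding genes with a mean of at least 100 counts and, between 2 groups, no overlap of the libraries. Among these Derl3, a membrane protein of ER-associated degradation, rose most (7.42 ± 0.13), followed by the ER oxidoreductase Creld2 (5.54 ± 0.13) and Sdf2l1, a cofactor of ER chaperones (5.46 ± 0.15). Tmem154 (5.21), Fibin (5.18), the linker histone gene Hist1h1d (4.84) and the stress transcription factor Atf3 (4.69) rose as well. Among the largest falls were those of Dio2, a thyroid hormone deiodinase (-4.69 ± 0.45), the growth factor receptor Pdgfra (-4.64 ± 0.29) and Thrsp (-4.08 ± 0.15).

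By list, 18 of 18 measured PERK-ATF4-CHOP targets rose in WT neurons (camera adjusted p = 7.44e-52). Among them were Atf4 (1.61 ± 0.08), the phosphatase subunit Ppp1r15a (3.70 ± 0.09), the pseudokinase Trib3 (4.08 ± 0.14) and the glutathione-degrading enzyme Chac1 (3.35 ± 0.09). Of 20 ER chaperones and folding enzymes 20 rose (1.04e-71). Examples are Pdia4 (4.84 ± 0.09), Hsp90b1 (4.02 ± 0.19) and Hyou1 (3.65 ± 0.09). IRE1-XBP1 targets rose in 20 of 21 cases (2.26e-25), with Xbp1 at 1.75 ± 0.10 and Dnajb9 at 3.60 ± 0.14. Transcripts of genes for amino acid supply and tRNA loading rose at 10 of 12 amino acid transporters (2.05e-17, Slc6a9 3.08 ± 0.10), 11 of 12 enzymes of amino acid synthesis and one-carbon metabolism (2.26e-25, Shmt2 3.00 ± 0.08) and 18 of 20 cytosolic aminoacyl-tRNA synthetases (9.36e-16, Tars 1.69 ± 0.08). Asns, which encodes asparagine synthetase, rose by 1.39 ± 0.08. Cytosolic ribosomal protein genes were higher in 62 of 79 cases (1.55e-06, adjusted p = 0.511 with an estimated correlation), such as Rplp0 (0.98 ± 0.11). Conversely, 22 of 22 genes of cholesterol synthesis and uptake fell (6.09e-32). Synaptic genes fell in 25 of 32 cases (4.41e-11, Stx1a -1.42 ± 0.08) and neuronal markers in 10 of 15 (2.8e-05, Tubb3 -1.38 ± 0.10).

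The neuronal cultures also held transcripts of other cell types, which moved with the treatment. Of 15 measured astrocyte markers 14 fell (camera adjusted p = 1.06e-12). The glutamate transporter Slc1a3 stood at 919.6 ± 41.9 CPM in controls and 162 ± 19.9 CPM with TM. Oligodendrocyte lineage markers fell in 11 of 12 cases and 1 rose, Mog (1.05e-05, adjusted p = 0.104 with an estimated correlation), with Olig1 at -2.17 ± 0.15. Adjusted over the list alone, the counts were 18 PERK-ATF4-CHOP targets, 20 chaperones, 20 IRE1-XBP1 targets, 10 transporters, 11 enzymes, 18 synthetases and 64 ribosomal protein genes higher. They were 22 cholesterol genes, 28 synaptic genes, 11 neuronal, 14 astrocyte and 11 oligodendrocyte lineage markers lower. In total 4203 genes rose and 3852 fell among 15546 tested. Of these, 1499 and 1514 changed over 2-fold, and the authors' deposited table called 7857 genes. Of the 33 lists, 24 passed with the preset correlation and 12 with an estimated one. None of the 67 named genes that passed was lost when any 1 library was left out.

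**Figure D2:**
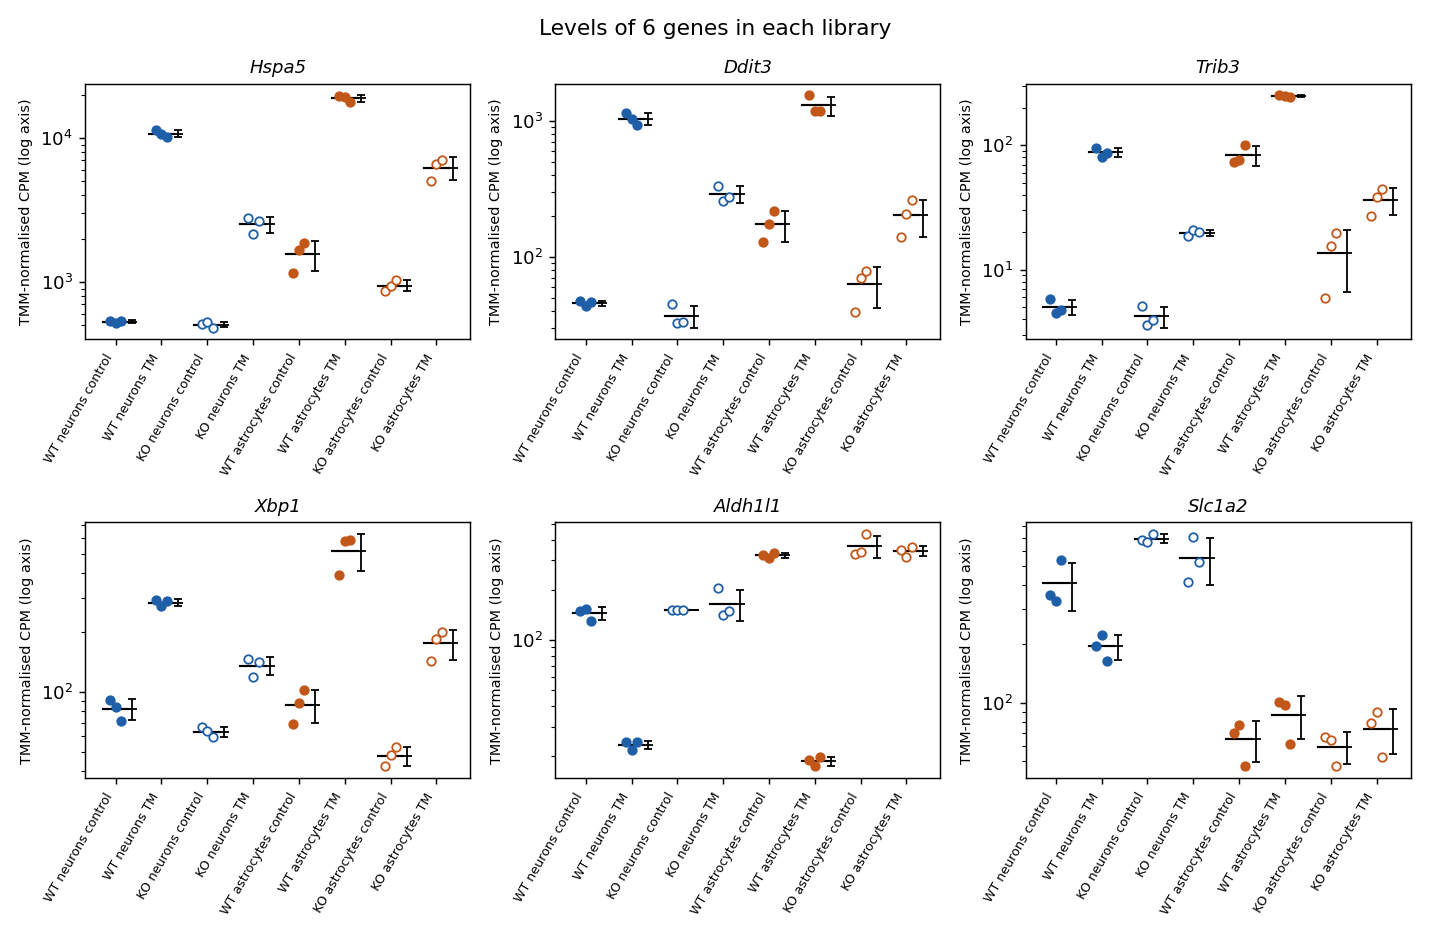
Levels of Hspa5, Ddit3, Trib3, Xbp1, Aldh1l1 and Slc1a2 in TMM-normalised CPM (vertical log axes) in each library (points) of the 8 groups (horizontal axis), with group means as lines and SDs as error bars (n = 3). Hspa5 went from 531 to 10715 with TM in WT neurons and from 506 to 2523 in Perk KO neurons, and Aldh1l1 from 323 to 18.6 in WT astrocytes and from 367 to 342 in Perk KO astrocytes.

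The same treatment in Perk KO neurons measured the response without most of the Eif2ak3 transcript. Hspa5 went from 506 ± 22.8 to 2523 ± 323 CPM, a 4.99-fold rise (2.32 ± 0.13, adjusted p = 0.000151), and Ddit3 from 37.2 ± 6.86 to 289 ± 40.1 CPM (7.76-fold). Atf3 rose most among genes ranked by size (4.13 ± 0.13), followed by the innate immune receptor Tlr2 (3.68 ± 0.30), the costimulatory ligand Icosl (3.40 ± 0.29) and the chemokine Ccl2 (3.21 ± 0.22). Among the largest falls were those of Stab1 (-3.19 ± 0.24), the potassium channel subunits Kcnv1 (-2.43 ± 0.18) and Kcng1 (-2.26 ± 0.23) and the neuronal transcription factor Neurod6 (-2.26 ± 0.17).

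PERK-ATF4-CHOP targets rose in 16 of 17 cases in Perk KO neurons (camera adjusted p = 1.24e-31). Atf4 rose by 0.96 ± 0.12, Trib3 by 2.22 ± 0.17, Chac1 by 1.89 ± 0.13 and Sesn2 by 1.52 ± 0.10. All 20 of 20 measured ER chaperones and folding enzymes rose (6.95e-39), including Hsp90b1 (1.58 ± 0.10) and Sdf2l1 (2.88 ± 0.17), as did 18 of 21 IRE1-XBP1 targets (4.61e-25, Dnajb9 2.15 ± 0.10, Xbp1 1.10 ± 0.11). Herpud1, a component of ER-associated degradation, rose by 1.82 ± 0.11. Amino acid transporters were higher in 11 of 12 cases (1.93e-17, Slc3a2 2.64 ± 0.14). NF-kB and cytokine genes rose in 12 of 14 cases (5.72e-14, adjusted p = 0.0753 with an estimated correlation), such as Cxcl10 (2.47 ± 0.21) and Cxcl1 (2.85 ± 0.25). Reactive astrocyte genes were higher in 14 and lower in 1, Iigp1, of 31 cases (1.18e-07, adjusted p = 0.295 with an estimated correlation), among them Steap4 (3.01 ± 0.26) and Gbp2 (2.10 ± 0.21). Neuronal markers fell in 12 of 15 cases (1.63e-07), with Nefh at -1.63 ± 0.15. Of 79 ribosomal protein genes 2 rose, Rpl10 (1.21 ± 0.19) and Rpl30 (0.75 ± 0.19; list 0.034, adjusted p = 0.765 with an estimated correlation). Rpl30 lost its call without control replicate 1 (0.0755), 2 (0.0983) or 3 (0.0776) and TM replicate 3 (0.0666).

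Adjusted over the list alone, these counts were 16, 20, 18, 11, 13, 18 and 1 higher for the PERK-ATF4-CHOP, chaperone, IRE1-XBP1, transporter, NF-kB, reactive astrocyte and ribosomal protein lists. There were 1 NF-kB and cytokine gene, 1 reactive astrocyte gene and 12 neuronal markers lower. In all, 2114 genes rose and 1744 fell among 16197 tested (607 and 429 over 2-fold). The authors' deposited table called 4058. Of the 33 lists 25 passed, and 5 with an estimated correlation. The total of 3858 was 1987, 2053 and 1972 without control replicate 1, 2 or 3, 5844 without TM replicate 2 and 2109 without TM replicate 3. The ribosomal protein list lost its call without control replicate 3 (adjusted p = 0.132) and after GC correction (0.0833), and turned to -0.02 without TM replicate 1 (0.597).

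What loss of Perk changed in unstressed cells was tested in control neurons. Of genes ranked by size, those that fell most beside Eif2ak3 itself were Pdgfra (-3.12 ± 0.27) and Nptx2 (-2.75 ± 0.12). Nptx2 went from 143 ± 2.17 CPM in WT to 21.3 ± 3.41 CPM in Perk KO. The proteoglycan gene Acan (-1.73), Fndc9 (-1.65) and Pgbd5 (-1.61) fell as well. Among the largest rises were Samd9l (2.42 ± 0.32), Nbeal1 (2.41 ± 0.33), Spp1 (2.26 ± 0.19) and Lox (2.19 ± 0.53).

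Of 17 measured PERK-ATF4-CHOP targets 1 was higher, Vldlr (0.62 ± 0.16), and 16 did not pass (camera adjusted p = 0.995, with the test downward and the median of 0.12 above 0). Atf4 differed by -0.24 ± 0.09 (adjusted p = 0.0862), Ddit3 by -0.31 ± 0.13 (0.129) and Trib3 by -0.26 ± 0.21 (0.401). Asns was lower (-0.31 ± 0.09, 0.0346). Of the 6 calls of fixed genes, 0 to 5 ended with 1 library left out, 5 without Perk KO control replicate 2 or 3. Ddit3 passed as lower after GC correction with the replicate block (-0.41, adjusted p = 0.00485) and without Perk KO control replicate 1 (-0.47, 0.0402). Of 20 ER chaperones and folding enzymes Hsp90b1 (0.74 ± 0.14) and Dnajc3 (0.93 ± 0.18) were higher and 18 did not pass (list 0.564), and Hspa5 differed by -0.08 ± 0.07 (adjusted p = 0.494). Activity-dependent immediate early genes were lower in 9 of 15 cases (2.13e-11, adjusted p = 0.247 with an estimated correlation), such as Arc (-1.08 ± 0.16) and Fos (-1.21 ± 0.20). Genes of cholesterol synthesis and uptake were lower in 17 of 22 (5.43e-16, adjusted p = 0.241 with an estimated correlation), with Acat2 at -0.92 ± 0.09. Markers of other cell types differed too. Oligodendrocyte lineage markers were lower in 6 and higher in 1 of 13 cases (0.00133, adjusted p = 0.477 with an estimated correlation). Sox10 stood at -3.27 ± 0.59. Fibroblast and mural cell markers were higher in 6 and lower in 1, Myl9, of 11 (0.00359, adjusted p = 0.239 with an estimated correlation), with Dcn at 1.74 ± 0.17. Microglia markers were higher in 7 of 13 (0.000403, adjusted p = 0.579 with an estimated correlation), with C1qb at 1.01 ± 0.21.

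Mitochondrially encoded genes were higher in 10 of 13 cases (camera adjusted p = 3.55e-07, adjusted p = 0.247 with an estimated correlation), with mt-Co2 at 0.78 ± 0.08, and took 5.57% to 5.92% of the counts in control Perk KO neurons against 3.26% to 4.05% in control WT neurons. After correction for the GC content of transcripts their direction turned: mt-Co2 was at -0.11 and the list median at -0.33 (adjusted p = 0.0899). The same correction turned Dnajb9 from 0.60 ± 0.12 to -0.07 and Ero1l from 0.29 ± 0.11 to -0.23, and ended the calls of Xbp1 (-0.39 ± 0.11, then -0.24 with adjusted p = 0.102) and Eif2b5 (-0.37 ± 0.11, then -0.22 with adjusted p = 0.117; 0.0515 with DESeq2's size factors). Across genes, the log2 difference and GC content were correlated (Spearman's rho = -0.44, genes not being independent replicates).

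Within each list adjusted alone, 0 PERK-ATF4-CHOP targets, 2 chaperones, 7 fibroblast and mural cell, 9 microglia and 10 mitochondrially encoded genes were higher, and 13 immediate early, 19 cholesterol and 7 oligodendrocyte lineage genes lower. Of 15757 genes tested 1927 were higher and 1443 lower in Perk KO (914 and 155 over 2-fold, and 359 and 211 after GC correction). The share of higher genes, 57.2%, was 68.7% without WT control replicate 2 and 71.3% without Perk KO control replicate 2. The authors' deposited table called 3462, and 0 of the 15 lists that passed did so with an estimated correlation. With the replicate number as a block, Ppp1r15a (adjusted p = 0.0429), Ero1l (0.0448), Hyou1 (0.0199) and Calr (0.0158) passed too. The total of 3370 was 695, 1710 and 5414 without WT control replicate 1, 2 or 3, and 1821, 589 and 257 without Perk KO control replicate 1, 2 or 3. In the same order, 12, 5, 0, 5, 17 and 21 of the 45 named genes that passed lost their call, and the microglia list did without WT control replicate 3 (adjusted p = 0.0841).

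Under TM, Perk KO neurons were compared directly with WT neurons. Ddit3 was lower in Perk KO (289 ± 40.1 against 1031 ± 97.7 CPM, log2 difference -1.77 ± 0.14), as were Hspa5 (2523 ± 323 against 10715 ± 569 CPM, -2.02 ± 0.17), Herpud1 (-2.53 ± 0.13) and Sdf2l1 (-2.61 ± 0.17). The largest differences below WT were those of Derl3 (-4.17 ± 0.19), Hist1h1d (-3.72 ± 0.29) and the focal adhesion gene Tes (-3.55 ± 0.12). The largest above WT were those of Dio2 (5.88 ± 0.54), Steap4 (5.21 ± 0.26), the matrix protease Mmp3 (5.08 ± 0.31), Ecm2 (5.05 ± 0.38) and the astrocytic water channel Aqp4 (4.91 ± 0.29, 343 ± 113 against 11.8 ± 3.29 CPM).

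Of 18 PERK-ATF4-CHOP targets 14 were lower (camera adjusted p = 1.03e-18, adjusted p = 0.0949 with an estimated correlation). Among them were the stress hormone gene Gdf15 (-2.63 ± 0.13), Trib3 (-2.09 ± 0.11), Nupr1 (-1.96 ± 0.10), the ER oxidase gene Ero1l (-1.92 ± 0.09) and Atf4 (-0.85 ± 0.12). ER chaperones and folding enzymes were lower in 17 of 20 cases (4.7e-24, adjusted p = 0.131 with an estimated correlation), with Creld2 at -3.16 ± 0.14 and Pdia4 at -2.93 ± 0.16. All 12 of 12 enzymes of amino acid synthesis and one-carbon metabolism were lower (1.99e-14, adjusted p = 0.153 with an estimated correlation), such as Cth (-2.10 ± 0.12). So were 18 of 20 aminoacyl-tRNA synthetases (3.39e-12, adjusted p = 0.221 with an estimated correlation), such as Vars (-1.32 ± 0.10). Among the eIF2 kinases, eIF2 and eIF2B, 6 of 12 were lower and 1 higher (0.00653, adjusted p = 0.254 with an estimated correlation): Eif2b3 stood at -1.13 ± 0.14, and Eif2ak2, the interferon-induced kinase PKR, at 2.36 ± 0.34. Astrocyte markers were higher in 16 of 16 cases (1.03e-24, adjusted p = 0.0949 with an estimated correlation), with Aldh1l1 at 2.88 ± 0.17. Reactive astrocyte genes were higher in 24 and lower in 2, Ptx3 and Ptgs2, of 30 (1.99e-14, adjusted p = 0.131 with an estimated correlation), with Serpina3n at 2.40 ± 0.16.

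Counts adjusted over the list alone were 14, 17, 12, 18 and 8 lower for the lists named as lower and 16 and 25 higher for the astrocyte lists, in the order given. Between genotypes under TM, 3314 genes were higher and 3113 lower in Perk KO among 16026 (1840 and 742 over 2-fold). The authors' deposited table called 6395. Of the 33 lists 24 passed, 0 of them with an estimated correlation. Eif2b5, which encodes the catalytic subunit of the exchange factor eIF2B, differed by -0.42 ± 0.15 with adjusted p = 0.053, and 0.0091 with the replicate number as a block.

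In WT astrocytes, the effect of TM on cells with intact Perk was measured in the same way. Hspa5 rose 11.9-fold from 1561 ± 374 to 18801 ± 978 CPM (3.57 ± 0.21, adjusted p = 2.34e-05), and Ddit3 rose 7.35-fold from 174 ± 44.6 to 1292 ± 210 CPM. Derl3 (8.35 ± 0.41), Sdf2l1 (6.12 ± 0.20), Creld2 (5.32 ± 0.22) and the ER prolyl isomerase Fkbp11 (4.41 ± 0.26) were among the largest rises. The largest falls were those of Cnmd (-6.06 ± 0.46), Sez6 (-5.49 ± 0.22), the insulin-like growth factor binding protein Igfbp5 (-5.36 ± 0.20, from 2696 ± 469 to 66.5 ± 6.67 CPM) and the mitochondrial glutamate carrier Slc25a18 (-5.17 ± 0.40).

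PERK-ATF4-CHOP targets rose in 17 of 18 cases (camera adjusted p = 1.68e-08, adjusted p = 0.251 with an estimated correlation). Ero1l rose by 2.45 ± 0.16, Atf4 by 1.82 ± 0.19, Trib3 by 1.56 ± 0.13 and Chac1 by 1.28 ± 0.23. All 20 of 20 ER chaperones and folding enzymes rose (7.59e-35, adjusted p = 0.138 with an estimated correlation), such as Manf (4.01 ± 0.16) and Hsp90b1 (4.17 ± 0.22). IRE1-XBP1 targets rose in 19 of 21 cases (4.44e-23, adjusted p = 0.138 with an estimated correlation), with Dnajb9 at 3.88 ± 0.13 and Xbp1 at 2.57 ± 0.20. The N-glycosylation machinery rose in 22 of 25 (1.93e-11, adjusted p = 0.234 with an estimated correlation), with Alg12 at 2.15 ± 0.13. Of 8 transcripts reported to be cleaved by IRE1 7 fell (0.000129, adjusted p = 0.121 with an estimated correlation), with Scara3 at -3.17 ± 0.18. Ribosomal protein genes were higher in 59 of 79 cases (2.5e-08, adjusted p = 0.542 with an estimated correlation), with Rpl12 at 1.02 ± 0.12. Markers of astrocytes themselves fell in 13 of 15 cases (4.68e-16, adjusted p = 0.11 with an estimated correlation). Aldh1l1 went from 323 ± 11.1 to 18.6 ± 1.23 CPM (-4.14 ± 0.11), and the sodium pump subunit Atp1b2 fell too (-3.74 ± 0.17). Cell cycle genes fell in 17 and rose in 1, Pcna, of 22 (0.0019, adjusted p = 0.456 with an estimated correlation), with Ccnd1 at -1.21 ± 0.15. Interferon-stimulated genes fell in 14 of 20 (0.00299, adjusted p = 0.599 with an estimated correlation), with Ifit3 at -2.55 ± 0.37.

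With adjustment over each list alone, the counts were 17, 20, 19, 22 and 62 higher for the lists that rose and 7, 13, 17 and 15 lower for those that fell, in the order given. TM changed 3728 genes upward and 4131 downward of 14907 tested (1066 and 2511 over 2-fold), against 7935 in the authors' deposited table. An estimated correlation left 0 of the 22 lists that passed. None of the 56 named genes that passed was lost when any 1 library was left out, and with the replicate number as a block Eif2b5 (0.21 ± 0.09, adjusted p = 0.0745) reached 0.0196.

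The TM response of astrocytes without most of the Eif2ak3 transcript was measured in Perk KO astrocytes. Hspa5 rose 6.58-fold from 945 ± 84.8 to 6229 ± 1087 CPM (2.72 ± 0.15) and Ddit3 3.19-fold from 63.1 ± 21 to 202 ± 60.9 CPM (1.67 ± 0.28). Derl3 (4.53 ± 0.31), Sdf2l1 (3.81 ± 0.20), Ccl3 (3.74 ± 0.49) and Slc2a6 (3.20 ± 0.18) had the largest rises. The largest falls were those of Oas2 (-3.85 ± 0.40), Id3 (-3.77 ± 0.20), Gfap (-3.57 ± 0.29) and Fbln2 (-3.07 ± 0.37). Gfap went from 879 ± 232 to 74 ± 27.3 CPM.

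Of 20 ER chaperones and folding enzymes 19 rose in Perk KO astrocytes (camera adjusted p = 1.98e-115), with Hsp90b1 at 2.47 ± 0.10 and Pdia6 at 2.04 ± 0.10. Of 21 IRE1-XBP1 targets 19 rose (1.09e-75), with Dnajb9 at 2.97 ± 0.11 and Xbp1 at 1.89 ± 0.14. The N-glycosylation machinery was higher in 19 of 25 cases (5.93e-38), with Alg2 at 1.72 ± 0.09. PERK-ATF4-CHOP targets rose in 8 of 17 cases (4.6e-06, adjusted p = 0.477 with an estimated correlation), among them Ero1l (0.90 ± 0.18) and Vldlr (0.78 ± 0.15). Aminoacyl-tRNA synthetases rose in 3 of 20 (0.00118, adjusted p = 0.607 with an estimated correlation), Rars (0.71 ± 0.17), Nars (0.58 ± 0.15) and Wars (0.47 ± 0.12). Without TM replicate 2, Ero1l and Vldlr lost their calls (adjusted p = 0.0538 and 0.0602). The 3 synthetases lost theirs, in that order, without TM replicate 2 (0.111, 0.146 and 0.146) or 3 (0.0874, 0.104 and 0.115) and control replicate 1 (0.0609, 0.0978 and 0.112) or 2 (0.0703, 0.117 and 0.105), and Wars did without control replicate 3 (0.0661). Interferon-stimulated genes fell in 18 of 20 cases (6.26e-32, adjusted p = 0.147 with an estimated correlation), such as Stat2 (-1.90 ± 0.17), Oasl2 (-2.88 ± 0.31) and Usp18 (-2.59 ± 0.28). Among 79 ribosomal protein genes 1 rose, Rpl10 (1.02 ± 0.12), and the list did not pass (0.0993).

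With adjustment over each list alone, 19, 20, 22, 12, 5 and 1 genes of those lists were higher, and 18 interferon-stimulated genes lower. In all, 841 genes rose and 698 fell of 15164 tested (243 and 245 over 2-fold), against 1886 in the authors' deposited table. Of 18 lists that passed 3 did with an estimated correlation too. With the replicate number as a block 2190 rose and 2098 fell (4288 in all). Chac1 (1.29 ± 0.37, adjusted p = 0.0577), Asns (0.89 ± 0.31, 0.111), Iars (0.57 ± 0.16, 0.0599), Rplp0 (0.108), Rpl4 (0.227) and the ribosomal protein list then passed, at 2.6e-07, 9.42e-07, 1.44e-05, 0.000923, 0.00555 and 0.0364. Without the block the total of 1539 was 890 without control replicate 2 and 807 without TM replicate 2. Atf4 (0.97 ± 0.23, adjusted p = 0.0302) lost its call without control replicate 1 (0.0608), and Atf4 and Trib3 (1.41 ± 0.36, 0.0389) lost theirs without control replicate 2 (0.0879 and 0.103), TM replicate 2 (0.109 and 0.117) and TM replicate 3 (0.086 and 0.102).

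In unstressed astrocytes Trib3 was lower in Perk KO (13.7 ± 7.03 against 83.3 ± 14.7 CPM in WT, log2 difference -2.60 ± 0.36). Chac1 (-2.59 ± 0.38), Asns (-1.85 ± 0.31), Ddit3 (-1.46 ± 0.27) and Atf4 (-1.38 ± 0.24) were lower too. Of the 11 fixed genes called, 0 to 10 lost their call when 1 library was left out, 10 without WT control replicate 2. Among the largest falls were those of Mx1 (-3.60 ± 0.53), Syt4 (-3.47 ± 0.44), Gbp4 (-3.13 ± 0.38) and Gbp5 (-2.99 ± 0.28). The largest rises, which were smaller, were those of Atp6v1c1 (2.01 ± 0.49), the mitotic gene Cenpf (1.57 ± 0.43) and Mal (1.49 ± 0.29).

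Of 18 PERK-ATF4-CHOP targets 16 were lower (camera adjusted p = 1.9e-19, adjusted p = 0.258 with an estimated correlation), such as Atf3 (-2.32 ± 0.28). Enzymes of amino acid synthesis and one-carbon metabolism were lower in 11 of 12 cases (1.6e-16, adjusted p = 0.258 with an estimated correlation; Aldh1l2 -2.41 ± 0.26). Amino acid transporters were lower in 9 of 12 cases (1.71e-16, adjusted p = 0.258 with an estimated correlation), with Slc1a5 at -2.03 ± 0.15. Aminoacyl-tRNA synthetases were lower in 17 of 20 (1.9e-19, adjusted p = 0.258 with an estimated correlation), with Iars at -1.48 ± 0.20. NF-kB and cytokine genes were lower in 13 of 15 (5.66e-24, adjusted p = 0.258 with an estimated correlation), among them the adhesion molecule Icam1 (-1.55 ± 0.12) and Ccl2 (-2.74 ± 0.31). Interferon-stimulated genes were lower in 16 of 20 (3.64e-13, adjusted p = 0.367 with an estimated correlation), such as Zbp1 (-2.34 ± 0.35). ER chaperones went both ways: 3 of 20 were higher, Creld2 (0.51 ± 0.12), Pdia6 (0.36 ± 0.10) and Sdf2l1 (0.65 ± 0.17), and 1 was lower, Hspa5 (-0.73 ± 0.18), with the list higher (0.00355, adjusted p = 0.427 with an estimated correlation).

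Within each list adjusted alone, 17, 12, 10, 18, 14 and 19 genes of those lists were lower, with 1 PERK-ATF4-CHOP target and 1 transporter higher, and of the chaperones 6 were higher and 1 lower. Of 15196 genes 716 were higher and 1544 lower in Perk KO (92 and 580 over 2-fold), against 2963 in the authors' deposited table. An estimated correlation left 0 of the 17 lists that passed. With the replicate number as a block, 2753 were higher and 2977 lower, so that the share of higher genes was 48.0% instead of 31.7%. Hsp90b1 (0.32 ± 0.09, adjusted p = 0.0506) and Eif2b5 (-0.28 ± 0.10, 0.0993) passed at 0.00912 and 0.022. The share of higher genes was 47.6% with GC correction and the block, 42.7%, 6% and 12.9% without WT control replicate 1, 2 or 3, and 20.4% and 11.3% without Perk KO control replicate 1 or 2. Without the block, the total of 2260 was 4138, 50 and 472 without WT control replicate 1, 2 or 3, and 658, 406 and 1211 without Perk KO control replicate 1, 2 or 3. In that order 0, 36, 12, 11, 13 and 6 of the 51 named genes that passed lost their call, and Pdia6 did when genes with low counts were kept (0.34, adjusted p = 0.0714).

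Under TM the difference between Perk KO and WT astrocytes was measured directly. Ddit3 stood at 202 ± 60.9 CPM in Perk KO and 1292 ± 210 CPM in WT (-2.66 ± 0.23), and Hspa5 at 6229 ± 1087 and 18801 ± 978 CPM (-1.57 ± 0.16). Trib3 (-2.74 ± 0.18), Chac1 (-2.56 ± 0.25), Asns (-2.36 ± 0.21) and Atf4 (-2.22 ± 0.20) were lower, and so was Eif2b5 (-0.48 ± 0.09, adjusted p = 0.00145). The largest differences above WT were those of the secreted protein Fgl2 (5.85 ± 0.40), the sulfotransferase Sult1a1 (5.78 ± 0.27) and Igfbp5 (5.71 ± 0.15), and the kinase gene Camk2a was higher by 5.00 ± 0.24. The largest below WT were those of the cytokine Il6 (-4.23 ± 0.62), Mx1 (-4.21 ± 0.62) and Syt4 (-4.18 ± 0.20).

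PERK-ATF4-CHOP targets were lower in 17 of 18 cases (camera adjusted p = 3.06e-12, adjusted p = 0.228 with an estimated correlation), with Ero1l at -2.92 ± 0.15 and Stc2 at -2.79 ± 0.23. Aminoacyl-tRNA synthetases were lower in 19 of 20 (3.33e-14, adjusted p = 0.225 with an estimated correlation), with Eprs at -2.11 ± 0.13. Of 79 ribosomal protein genes 61 were lower (3.27e-10, adjusted p = 0.638 with an estimated correlation), such as Rpl7a (-1.87 ± 0.12). Of 32 other initiation and elongation factors 29 were lower and 2 higher, Eif4ebp2 and Eef1a2 (1.42e-06, adjusted p = 0.225 with an estimated correlation), with Eif4ebp1 at -1.63 ± 0.15 and Eef1a2, the elongation factor form of neurons and muscle, at 3.36 ± 0.27. ER chaperones and folding enzymes were lower in 13 and higher in 2, Cnpy3 and Fkbp2, of 20 (0.000482, adjusted p = 0.663 with an estimated correlation), with Creld2 at -2.33 ± 0.22. Interferon-stimulated genes were lower in 17 of 20 (0.00188, adjusted p = 0.696 with an estimated correlation), with Isg15 at -2.97 ± 0.50. Astrocyte markers were higher in 14 of 15 (1.2e-12, adjusted p = 0.129 with an estimated correlation), with Aldh1l1 at 342 ± 24.7 CPM in Perk KO and 18.6 ± 1.23 CPM in WT (4.22 ± 0.12).

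Within each list adjusted alone, 17, 19, 61, 29, 13 and 18 were lower in that order and 14 astrocyte markers higher. This comparison gave the most calls of the 8, with 4797 genes higher and 4659 lower among 14927 tested (3028 and 1731 over 2-fold), against 9543 in the authors' deposited table. Of the 18 lists that passed 0 did so with an estimated correlation, and none of the 54 named genes that passed was lost when any 1 library was left out.

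**Figure D3:**
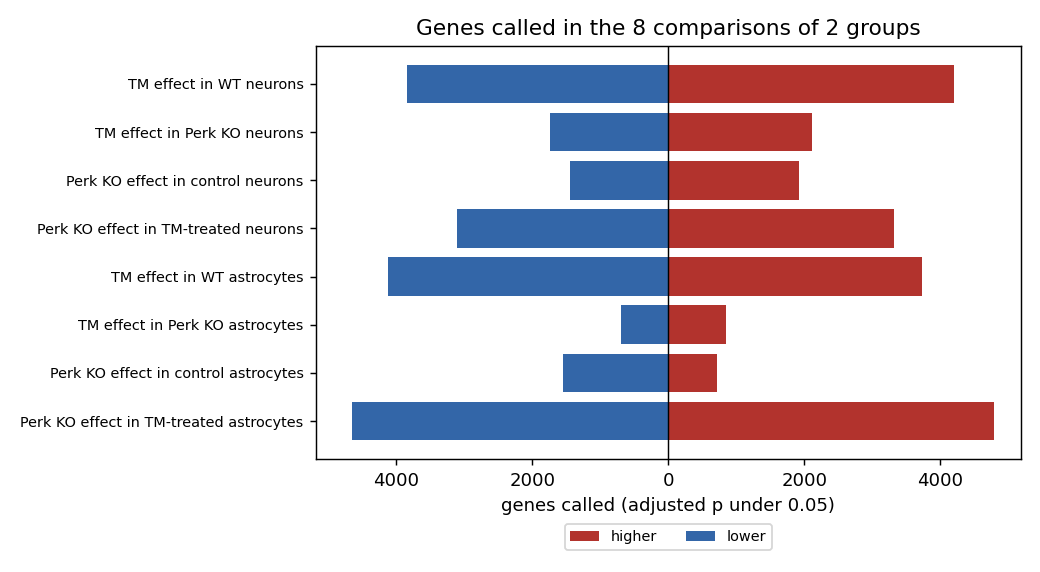
Number of genes called higher (bars to the right) and lower (bars to the left) at an adjusted p under 0.05 in edgeR (horizontal axis, genes) for the 8 comparisons of 2 groups. Without the replicate block totals ranged from 1539 (TM in Perk KO astrocytes) to 9456 (Perk KO in TM-treated astrocytes). With it the 1539 were 4288, not the lowest.

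Whether the TM response itself differed between genotypes was tested as an interaction, positive where Perk KO cells responded more upward. In neurons the interaction was -2.02 ± 0.15 for Hspa5 (adjusted p = 3.98e-06), -1.53 ± 0.19 for Ddit3 (0.000128), -2.43 ± 0.13 for Herpud1 (4.59e-07) and -2.61 ± 0.22 for Sdf2l1 (1.17e-05), so that each rose less in Perk KO neurons. The interactions of Hist1h1d (-4.69 ± 0.41), Derl3 (-4.61 ± 0.35), Tes (-3.99 ± 0.16) and the peroxisomal oxidase Acox2 (-3.89 ± 0.38) were the most negative. Those of Pdgfra (4.32 ± 0.41), Ecm2 (4.22 ± 0.46) and the activity-dependent transcription factor Npas4 (3.96 ± 0.39) were among the most positive. PERK-ATF4-CHOP targets had a negative term in 14 of 18 cases (camera adjusted p = 5.05e-16; Ppp1r15a -1.59 ± 0.11). Chaperones did in 17 of 20 (4.36e-27; Pdia4 -3.05 ± 0.16), and amino acid synthesis and one-carbon enzymes in 10 of 12 (3.72e-11; Cth -2.17 ± 0.15). Astrocyte markers had a positive term in 14 of 15 cases (1.13e-19; Slc1a3 1.31 ± 0.13), and cholesterol genes in 17 with 1, Mvd, negative of 21 (4.49e-14). When each list was adjusted alone, 16, 17 and 11 were negative and 15 and 17 positive. In total 2304 genes had a positive and 2449 a negative term of 15939 tested, and 8 of 24 lists passed with an estimated correlation too.

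**Figure D4:**
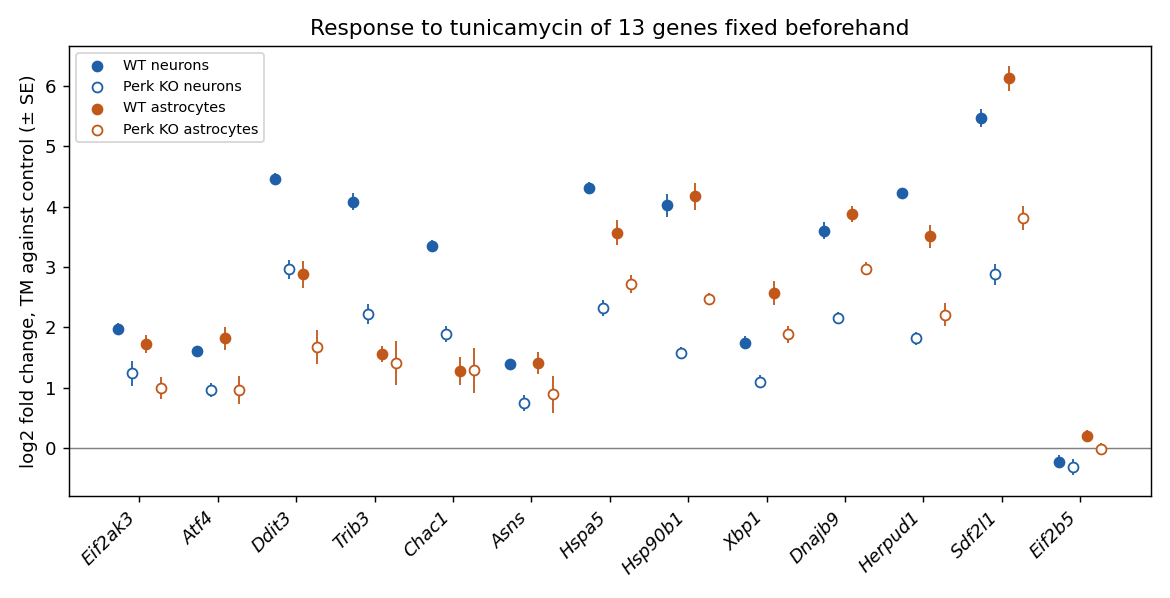
Log2 fold change of TM against control (vertical axis) of the 13 fixed genes (horizontal axis) in WT and Perk KO neurons and astrocytes, as points with standard errors from edgeR (3 against 3 libraries). Sdf2l1 changed by 5.46 in WT and 2.88 in Perk KO neurons and by 6.12 and 3.81 in WT and Perk KO astrocytes.

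In astrocytes the same interaction was -1.72 ± 0.22 for Hsp90b1 (adjusted p = 0.000133), -2.32 ± 0.26 for Sdf2l1 (5.68e-05), -0.87 ± 0.25 for Hspa5 (0.0176) and -1.22 ± 0.39 for Ddit3 (0.0305). Trib3 (-0.17 ± 0.43, 0.795) and Chac1 (0.00 ± 0.33, 0.999) did not pass. The most negative terms were those of Derl3 (-3.82 ± 0.64), Acox2 (-2.96 ± 0.51) and Zcchc12 (-2.88 ± 0.50), and the most positive those of Fgl2 (5.82 ± 0.56), Sult1a1 (5.18 ± 0.33) and Igfbp5 (5.10 ± 0.24). Chaperones had a negative term in 14 of 20 cases (camera adjusted p = 5.89e-10, adjusted p = 0.289 with an estimated correlation). PERK-ATF4-CHOP targets did in 3 of 18 (0.0153, adjusted p = 0.702 with an estimated correlation; Ero1l -1.57 ± 0.26, Sesn2 -0.54 ± 0.18 and Ddit3), and amino acid synthesis and one-carbon enzymes in 8 of 12 (2.62e-05, adjusted p = 0.311 with an estimated correlation; Gpt2 -1.08 ± 0.13). Astrocyte markers had a positive term in 10 of 15 (5.23e-14, adjusted p = 0.0542 with an estimated correlation; Acsbg1 2.32 ± 0.15). Cell cycle genes did in 11 with 1, Pcna (-0.59 ± 0.11), negative of 22 (0.00755, adjusted p = 0.547 with an estimated correlation; Mcm5 1.41 ± 0.21). When each list was adjusted alone, 15, 1 and 9 were negative (and 1 chaperone positive), and 11 and 15 positive. In total 2992 genes had a positive and 2211 a negative term of 15114. With the replicate number as a block Atf4 (-0.86 ± 0.34, 0.0647), Asns (-0.54 ± 0.41, 0.332) and Xbp1 (-0.69 ± 0.26, 0.0577) passed, at 0.000506, 0.0413 and 0.000206. The PERK-ATF4-CHOP list lost its call without Perk KO control replicate 3 (0.0702) and without Perk KO TM replicate 1 (0.051). Sesn2 lost its call without WT control replicate 1 (0.0658), WT TM replicate 2 (0.0678), Perk KO control replicate 2 (0.0618) or 3 (0.0691) and Perk KO TM replicate 1 (0.0825) or 2 (0.0614). Ddit3 lost its call without WT control replicate 1 (0.0664) or 2 (0.0552), WT TM replicate 1 (0.0549), Perk KO control replicate 2 (0.0684) or 3 (0.0786), and Perk KO TM replicate 1 (0.0681) or 2 (0.0556).

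Whether neurons and astrocytes differed in their TM response was tested as an interaction with cell type, positive where neurons responded more upward. In WT cells Trib3 rose more in neurons (2.35 ± 0.19, adjusted p = 9.98e-06), as did Chac1 (1.89 ± 0.27), Ddit3 (1.40 ± 0.24), Atf3 (3.00 ± 0.34) and Gdf15 (2.86 ± 0.28). Of 18 PERK-ATF4-CHOP targets 14 had a positive term (camera adjusted p = 2.94e-11, adjusted p = 0.184 with an estimated correlation). Xbp1 (-0.99 ± 0.23) and Sdf2l1 (-0.84 ± 0.23) had negative terms, and so had 5 of 20 chaperones, Sdf2l1 with Txndc11 (-0.91 ± 0.16), Hyou1 (-0.80 ± 0.21), Calr (-0.84 ± 0.24) and Fkbp2, though that list did not pass (0.0684). Cholesterol genes had a negative term in 18 of 21 cases (1.49e-26; Mvd -2.86 ± 0.20), and NRF2 targets, genes of the oxidative stress response, a positive one in 7 of 12 (0.00057, adjusted p = 0.147 with an estimated correlation; Gstm1 1.5 ± 0.16). The most positive term was that of Hist1h1d (6.23 ± 0.41), and among the most negative was that of Rph3a (-4.54 ± 0.86). When each list was adjusted alone, 14 PERK-ATF4-CHOP and 7 NRF2 targets were positive and 5 chaperones and 20 cholesterol genes negative. In total 1947 genes had a positive and 1970 a negative term of 15712, and 1 of 18 lists passed with an estimated correlation too. The share of positive terms, 49.7%, was 69.1% without the filter on low counts (2663 and 1190 genes) and 63.6% without WT astrocyte control replicate 1 (2130 and 1219), and 48.5% to 55.8% in all other settings. Eif2b5 (-0.61 ± 0.15, 0.01) lost its call when genes with low counts were kept (0.104). Sdf2l1 (0.0575) and Hyou1 (0.0504) lost their calls without WT astrocyte control replicate 1. Calr did without WT neuron control replicate 1 (0.0512), WT neuron TM replicate 2 (0.055) and WT astrocyte control replicate 2 (0.0546), and the chaperone list passed without WT neuron control replicate 3 (0.0475) and WT astrocyte TM replicate 2 (0.0334) or 3 (0.00363).

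In Perk KO cells the same test gave a positive term for Ddit3 (1.29 ± 0.36, adjusted p = 0.0365) and Atf3 (3.04 ± 0.33), and a negative one for Hsp90b1 (-0.88 ± 0.14), Dnajb9 (-0.82 ± 0.14), Sdf2l1 (-0.92 ± 0.27) and Xbp1 (-0.78 ± 0.19). Gfap (3.55 ± 0.40), Steap4 (3.19 ± 0.57) and Disp3 (3.10 ± 0.26) had the most positive terms. Sla (-3.81 ± 0.81) had 1 of the 8 most negative. Gfap (-3.57) and most interferon-stimulated genes fell in Perk KO astrocytes, which itself raises their terms. PERK-ATF4-CHOP targets had a positive term in 6 of 17 cases (camera adjusted p = 7.35e-05, adjusted p = 0.344 with an estimated correlation; Sesn2 1.11 ± 0.15). Reactive astrocyte genes did in 12 of 32 (1.06e-08, adjusted p = 0.185 with an estimated correlation; Gbp2 2.99 ± 0.27). The term was positive for 8 of 20 interferon-stimulated genes (4.1e-10, adjusted p = 0.269 with an estimated correlation; Ifit3 2.36 ± 0.38) and for 8 of 16 apoptosis regulators (5.34e-05, adjusted p = 0.134 with an estimated correlation; the BH3-only genes Bbc3 1.74 ± 0.16 and Bcl2l11 1.74 ± 0.22). By adjustment over the list alone, 6, 16, 16 and 8 were positive. Of 16059 genes 1108 had a positive and 767 a negative term, and 0 of 20 lists passed with an estimated correlation too. The share of positive terms was 59.1%, 47.7% without the filter on low counts and 48.9% after GC correction, which also ended the call of Dnajb9 (-0.55, adjusted p = 0.0796). The total of 1875 was 1010, 1155, 3383 and 1220 without Perk KO neuron control replicate 1, control replicate 3, TM replicate 2 and TM replicate 3, and 1010 without Perk KO astrocyte TM replicate 2. Ddit3 lost its call (0.0518 to 0.0886) without any 1 library except Perk KO neuron TM replicate 2, Perk KO astrocyte control replicate 1 and TM replicate 3. Sdf2l1 did (0.0525 to 0.089) without any except Perk KO neuron TM replicates 2 and 3, Perk KO astrocyte control replicate 1 and TM replicate 1, and Xbp1 did without Perk KO astrocyte TM replicate 2 (0.0563).

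Whether loss of Perk altered the TM response differently in neurons and astrocytes was tested as a 3-way interaction, positive where the neuronal interaction was higher. Msmo1 (1.34 ± 0.22, adjusted p = 0.000666) and Nsdhl (1.57 ± 0.28) had positive terms, as had 10 of 21 cholesterol genes (camera adjusted p = 3.56e-15, adjusted p = 0.0517 with an estimated correlation). Of the immediate early genes 2 of 15 passed, Nptx2 (3.94 ± 0.98) and Fosb (3.06 ± 0.85), both positive (0.00107, adjusted p = 0.932 with an estimated correlation), and of 20 interferon-stimulated genes Oasl2 did (3.22 ± 0.81; list 0.000234, adjusted p = 0.932 with an estimated correlation). Of the PERK-ATF4-CHOP targets Gdf15 passed (-2.27 ± 0.52), while Trib3 (-1.60 ± 0.53, 0.0825), Ddit3 (-0.18 ± 0.46, 0.886) and Atf4 (0.31 ± 0.38, 0.715) did not, and the list passed at 0.0499 (adjusted p = 0.932 with an estimated correlation). Among the most negative terms were those of the muscarinic receptor Chrm4 (-6.29 ± 0.88) and the adrenergic receptor Adra2c (-4.78 ± 0.50). By adjustment over the list alone, 14 cholesterol genes, 7 immediate early genes and 1 interferon-stimulated gene were positive, and 1 PERK-ATF4-CHOP target negative. Of 15924 genes 332 had a positive and 546 a negative term. The share of positive terms was 37.8%, and 25.4% without the filter on low counts, 46.1% with DESeq2's size factors, 51.9% with DESeq2, 42.1% with the replicate block, 51.2% after GC correction and 53.6% with both. When a library was left out it ranged from 22% (WT neuron control replicate 1) to 41.8%, with 24% without WT neuron control replicate 2 and 23.8% without Perk KO neuron TM replicate 1 or Perk KO astrocyte control replicate 2. Of 9 lists that passed 0 did with an estimated correlation too. Nptx2 lost its call without Perk KO astrocyte control replicate 2 (0.057). Fosb lost its call without any 1 library (0.0515 to 0.078) except WT neuron control replicate 3 and TM replicate 3, Perk KO neuron control replicate 1 and TM replicate 2, WT astrocyte control replicates 1, 2 and 3 and TM replicate 1, and Perk KO astrocyte control replicate 3 and TM replicate 3. Hspa5 (-1.02 ± 0.30, 0.0477) lost its call with DESeq2's size factors (0.0512), after GC correction (0.0505), and without any 1 library (0.0518 to 0.0871) except Perk KO neuron TM replicate 1, WT astrocyte control replicate 1 and TM replicate 1, and Perk KO astrocyte control replicate 3 and TM replicate 1. The PERK-ATF4-CHOP list lost its call after GC correction (0.0682) and without any 1 library (0.0507 to 0.302) except WT neuron TM replicate 2, Perk KO neuron control replicate 2 and TM replicate 3, WT astrocyte control replicate 1 and TM replicates 2 and 3, and Perk KO astrocyte control replicates 2 and 3 and TM replicate 1.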

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

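The results in this part are differences between groups that passed a test of the difference itself, an interaction in edgeR, and the splits of the libraries were planned; only the look at which labels the splits exchanged and the splits within replicate numbers were chosen after their results were seen. Values are log2 differences between responses. In neurons the TM response differed between genotypes for 4753 genes, among them Eif2ak3 (-0.78), Atf4 (-0.68), Ddit3 (-1.53), Trib3 (-1.90), Chac1 (-1.49), Asns (-0.68), Hspa5 (-2.02), Hsp90b1 (-2.47), Xbp1 (-0.68), Dnajb9 (-1.49), Herpud1 (-2.43) and Sdf2l1 (-2.61). In astrocytes it differed for 5203 genes, among them Eif2ak3 (-0.75), Ddit3 (-1.22), Hspa5 (-0.87), Hsp90b1 (-1.72), Dnajb9 (-0.93), Herpud1 (-1.31) and Sdf2l1 (-2.32). Between cell types it differed for 3917 genes in WT cells, among them Ddit3 (1.40), Trib3 (2.35), Chac1 (1.89), Xbp1 (-0.99), Sdf2l1 (-0.84) and Eif2b5 (-0.61), and for 1875 genes in Perk KO cells, among them Ddit3 (1.29), Hsp90b1 (-0.88), Xbp1 (-0.78), Dnajb9 (-0.82) and Sdf2l1 (-0.92). The genotype effect on the response differed between cell types for 878 genes, among them Hspa5 (-1.02). The call of Eif2ak3 in astrocytes ended without Perk KO control replicate 2 (adjusted p = 0.0522). Those of Ddit3 in astrocytes, Sdf2l1 and Eif2b5 in WT cells, Ddit3, Sdf2l1, Xbp1 and Dnajb9 in Perk KO cells and Hspa5 in the last test ended without single libraries or under other settings, each given in the report.

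Labels were exchanged at random in 40 splits for each test, the real one included: genotype within treatments (and cell types), or TM within cell types. As many genes as in the real split were called in 1 of 40 for the neuronal genotype by TM interaction (4753, highest other 3365). For that of astrocytes it was 4 of 40 (5203, highest other 7702). The cell type by TM interaction had 1 of 40 in Perk KO cells (1875, highest other 474). In WT cells it was 2 of 40 (3917, highest other 4564). The 3-way interaction had 4 of 40 (878, highest other 5092). The splits with the highest counts point to a structure of the samples: each exchanged more labels in 1 treatment or cell type than in another, which leaves part of the plain effect of genotype or TM in the term tested. Of the splits with equal exchanges, 17 and 18 in the genotype by TM interactions of neurons and astrocytes, and 19 and 20 in the cell type by TM interactions of WT and Perk KO cells, the highest count was 0, and the 3-way interaction had no such split. These splits exchanged labels across replicate numbers and used the fit without the replicate block.

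Since the numbers pair all astrocyte groups and the genotypes of neurons within a treatment, labels were also exchanged only within a number where they do. For the neuronal genotype by TM interaction 2 of 32 splits called as many genes as the real one. This held without the block (4753, highest other 7899) and with it (5114, highest other 8191). In the cell type by TM interaction of Perk KO cells TM was exchanged freely in neurons. There 2 of 80 splits called as many genes without the block (1875, highest other 3562). With the block 2 of 80 did (2777, highest other 4399). For the astrocyte genotype by TM interaction 5 of 32 did with the block (7449, highest other 10855). The other splits that called as many genes exchanged 2 or 3 more labels in 1 treatment or cell type than in the other. Of splits with equal exchanges, 9, 27 and 9 in these 3 tests, the highest count was 0. As above, these shares do not test the interaction alone, and chance was not excluded.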

How the results depend on the processing

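The GC-corrected settings were added, and their tests chosen, after the data were seen; all other settings were planned. Of 654 tests of named genes per setting, 635 had the same direction and side of the threshold without the filter on low counts, 645 with DESeq2's size factors in edgeR, 638 with DESeq2, 627 with the replicate block, 625 after GC correction and 611 after GC correction with the replicate block. The calls that ended without a change of direction numbered 3, 2, 1, 1, 4 and 0, and those gained 15, 4, 12, 25, 14 and 32. Over all left-out libraries 5267 stood, 341 ended, 40 were gained and 46 turned direction. Of 87 tests of described lists, 83 to 86 stood under each setting, and 675 did over all left-out libraries, where 19 ended and 5 were gained. Where no cause is named, the cause was not tested. Leaving out a library removes 1 of 6 libraries from a comparison of 2 groups, which lowers the number of calls by itself. The pseudocount alternative did not apply, since counts were deposited. No scaling moved the median of all tested genes by over 0.1.

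The number of genes called moved by over 1.5 times under some settings. With the replicate block it was 4288 for TM in Perk KO astrocytes, 5730 for Perk KO in control astrocytes and 1842 for the 3-way interaction. After GC correction with the replicate block it was 4368, 5720 and 2500 for these and 3118 for the cell type by TM interaction in Perk KO cells. DESeq2 called 1531 genes in the 3-way interaction. When each library was left out in turn, the number, whether it moved by that much or not, ranged from 6649 to 8719 for TM in WT neurons, 1972 to 5844 for TM in Perk KO neurons, 257 to 5414 for Perk KO in control neurons, 4620 to 6977 for Perk KO in TM-treated neurons, 6185 to 8223 for TM in WT astrocytes, 807 to 1321 for TM in Perk KO astrocytes, 50 to 4138 for Perk KO in control astrocytes and 8175 to 9956 for Perk KO in TM-treated astrocytes. It ranged from 3700 to 5721 and 4165 to 5833 for the genotype by TM interactions in neurons and astrocytes, 3064 to 4450 and 1010 to 3383 for the cell type by TM interactions in WT and Perk KO cells, and 623 to 1149 for the 3-way interaction.

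Directions turned in the effect of Perk KO in control neurons after GC correction, without and with the replicate block: Dnajb9 at -0.07 and -0.07, Sdf2l1 at 0.10 and 0.11, Ero1l at -0.23 and -0.23, mt-Co2 at -0.11 and -0.08, mt-Co1 at -0.09 and -0.07, mt-Cytb at -0.21 and -0.20, mt-Nd4 at -0.33 and -0.29, and the mitochondrially encoded list at -0.33 and -0.29. The PERK-ATF4-CHOP list there, whose test pointed down with a median of 0.12, pointed up with DESeq2's size factors (0.13), DESeq2 (0.13) and the replicate block (0.11), and its median was -0.08 in both GC-corrected settings. None of its values passed. Values close to 0 that changed sign without passing were those of Eif2b5 with TM in Perk KO astrocytes (GC-corrected 0.01, with the replicate block 0.02), and of Chac1 in the astrocyte genotype by TM interaction (-0.02 with DESeq2's size factors, -0.02 with DESeq2, -0.18 GC-corrected, -0.17 with the block too). Others were Atf4 in the cell type by TM interaction of Perk KO cells (-0.06 without the filter, -0.05 with DESeq2's size factors, -0.05 with DESeq2, -0.11 in both GC-corrected settings) and Asns in the 3-way interaction (0.03 with DESeq2's size factors, DESeq2 and GC correction, 0.01 with the replicate block, 0.05 GC-corrected with the block).

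Signs also turned when a library was left out, over the following ranges. In Perk KO neurons with TM the ribosomal protein list spanned -0.02 to 0.36. For Perk KO in control neurons Sdf2l1 spanned -0.18 to 0.02 and the PERK-ATF4-CHOP list -0.03 to 0.19, while Dnajb9 (0.48 to 0.73), Ero1l (0.23 to 0.44), mt-Co2 (0.75 to 0.83), mt-Co1 (0.58 to 0.74), mt-Cytb (0.53 to 0.70), mt-Nd4 (0.54 to 0.69) and the mitochondrially encoded list (0.53 to 0.69) had 1 sign. Eif2b5 spanned -0.06 to 0.08 with TM in Perk KO astrocytes, and Trib3 -0.52 to 0.19 and Chac1 -0.34 to 0.31 in the astrocyte genotype by TM interaction. In the cell type by TM interactions, Eif2ak3 (-0.04 to 0.22) and Asns (-0.35 to 0.09) turned in WT cells and Atf4 (-0.20 to 0.19) and Asns (-0.42 to 0.15) in Perk KO cells. In the 3-way interaction Eif2ak3 spanned -0.12 to 0.21, Ddit3 -0.39 to 0.07, Asns -0.30 to 0.28, Sdf2l1 -0.31 to 0.00 and Eif2b5 0.00 to 0.34.

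The replicate number as a block changed no other call of a gene named in the text or described list, where the numbers were taken to pair libraries, than those given beside the results. Between TM and control in neurons the numbers did not pair the libraries (correlations of 0.26, -0.35 and -0.28 in WT and 0.26, -0.12 and 0.03 in Perk KO, with 19 of 36 best matches to the own number over all neuron groups). The block there gave 7312 genes for TM in WT neurons, 3393 for TM in Perk KO neurons, 5114 for the neuronal genotype by TM interaction, and 4803 and 2777 for the cell type by TM interactions in WT and Perk KO cells. There the replicate block ended the call of Rnf181 in the neuronal genotype by TM interaction (adjusted p = 0.0501), and in the 3-way interaction Trib3 (0.023), Chac1 (0.0047), Herpud1 (0.0243), Fos (0.015), Bdnf (0.000857), Rtp4 (0.0199), Rsad2 (0.00477) and Stc2 (0.00881) passed with it. Among the calls of fixed genes gained under other settings were these. In the cell type by TM interaction of WT cells Hspa5 and Herpud1 passed without the filter (0.70 and 0.68), with DESeq2's size factors and DESeq2 (0.60 and 0.58) and GC-corrected (0.60 and 0.57, with the block 0.58 and 0.55), and Dnajb9 GC-corrected with the block (-0.37). In that of Perk KO cells Herpud1 (-0.54) and Eif2b5 (-0.49) passed GC-corrected with the block. In the astrocyte genotype by TM interaction Atf4 and Xbp1 passed without the filter (-0.86 and -0.69), with DESeq2 (-0.88 and -0.71) and in both GC-corrected settings, where Eif2b5 (-0.33) did too. In the 3-way interaction Trib3 passed without the filter (-1.60) and with DESeq2 (-1.56). Eif2b5 passed after GC correction with TM in WT (-0.25) and Perk KO neurons (-0.44).

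At this depth 15546 of 27507 genes with a count had a mean of at least 10 for TM in WT neurons.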

Other observations

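In this part the tests on GC content, on genomic DNA, on the share of astrocytes, on induced genes that take counts and on cells with intact Perk were chosen after the data were seen, as was the choice of lists described here, while the splits were planned. Further gene lists moved with TM. In WT neurons 19 of 22 cell cycle genes fell (median log2 change -1.52, camera adjusted p = 7.11e-08, adjusted p = 0.0793 with an estimated correlation), 13 of 15 activity-dependent immediate early genes fell and 1, Ier2, rose (-1.34, 1.31e-07, adjusted p = 0.104 with an estimated correlation), and 14 of 19 interferon-stimulated genes fell and 1, Bst2, rose (-1.16, 0.0021, adjusted p = 0.413 with an estimated correlation). In Perk KO neurons 9 of 16 apoptosis regulators rose (0.37, 1.03e-05, adjusted p = 0.0539 with an estimated correlation). Of 21 genes of cholesterol synthesis and uptake 15 fell there (-0.91, 1.17e-14, adjusted p = 0.135 with an estimated correlation). In Perk KO astrocytes 6 of 15 astrocyte markers fell (list median -0.29, 1.28e-07, adjusted p = 0.145 with an estimated correlation), Gfap among them. Adjusted over the list alone the counts were 19, 13 and 14 lower, 10 higher, and 16 and 7 lower.

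Between genotypes under TM, Perk KO neurons had 12 of 19 interferon-stimulated genes higher (median log2 difference 1.10, camera adjusted p = 0.000263, adjusted p = 0.262 with an estimated correlation) and 9 of 11 microglia markers higher (1.63, 0.00104, adjusted p = 0.423 with an estimated correlation). Perk KO astrocytes under TM had 17 of 24 synaptic genes higher and 1, Dlg4, lower (1.43, 2.48e-05, adjusted p = 0.129 with an estimated correlation), with Camk2a at 5.00 ± 0.24. All 12 of 12 enzymes of amino acid synthesis and one-carbon metabolism were lower there (-2.38, 2.64e-15, adjusted p = 0.129 with an estimated correlation), with Aldh1l2 at -3.78 ± 0.20. Adjusted over the list alone, 12, 10 and 18 were higher and 12 lower. Responses that share no library were compared across genes, which are not independent replicates. The TM responses of WT neurons and WT astrocytes had a Pearson correlation of 0.65, with 2235 genes called higher in both (1044 if calls were independent) and 2111 lower in both (929). For Perk KO neurons and astrocytes it was 0.29, with 488 (117) and 183 (69). The effects of Perk KO in neurons and astrocytes had a correlation of 0.09 in controls, with 144 (89) higher and 156 (129) lower in both, and 0.66 under TM, with 2376 (992) and 2119 (919).

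The 6 libraries of a comparison of 2 groups can be split in 10 ways, too few for a share under 0.05. The real split, the 1 of 10 with as many genes, gave 8055 genes for TM in WT neurons, 3858 for TM in Perk KO neurons, 3370 for Perk KO in control neurons, 6427 for Perk KO in TM-treated neurons, 7859 for TM in WT astrocytes, 1539 for TM in Perk KO astrocytes, 2260 for Perk KO in control astrocytes and 9456 for Perk KO in TM-treated astrocytes. The other splits, which mix the groups, called 0 genes in each.

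In control Perk KO neurons 914 genes were over 2-fold higher and 155 over 2-fold lower, with a median GC content of 40.9% in the former against 50.2% in genes not called. Genomic DNA in the libraries was excluded as the cause: it covers every gene alike, and olfactory receptor genes, which neurons and astrocytes hardly transcribe, had at most 0.0175 RPKM in a control Perk KO neuron library, against a median gain of 1.53 in the higher genes. A look taken before, at biotypes, did not decide: 5.01% of non-coding genes and pseudogenes (95% interval 4.07% to 6.09%) and 5.91% of protein-coding genes (5.52% to 6.31%) were over 2-fold higher. After GC correction 359 genes were over 2-fold higher and 211 lower, and with the replicate block 435 and 233 (1037 and 172 with the block alone), so that a GC-dependent difference between libraries may account for much of the excess. Deviations from the mean of the neuron libraries correlated with GC content at -0.31, -0.28 and -0.32 in the control Perk KO libraries and at 0.32, 0.42 and -0.06 in the control WT libraries. An effect of Perk loss on AT-rich transcripts stays open, untested, since the correction removes it as well. Without WT control replicate 1, 2 or 3 the 914 higher genes were 305, 547 and 1494, and without Perk KO control replicate 1, 2 or 3 they were 701, 347 and 113.

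In WT astrocytes TM lowered 13 of 15 astrocyte markers (median log2 change -2.55). A lower share of astrocytes in the cultures stays open. It raises markers of other cell types, and 23 of 42 of these passed as lower (upper quartile -0.94), but TM itself may lower these. The test on induced genes that take counts cannot decide, since TMM removes shifts that such genes cause. The 10 highest genes took at most 6.9% of the counts in a TM-treated WT astrocyte library. Also open is the hypothesis that the stress response of WT cells, through PERK, may lower the markers: the term for a response more upward in Perk KO was positive for 10 of 15 markers (camera adjusted p = 5.23e-14, adjusted p = 0.0542 with an estimated correlation). Whether dying cells or lower transcription lay behind the fall was not tested.

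In Perk KO neurons 16 of 17 PERK-ATF4-CHOP targets rose with TM. For these 17, all of which rose in WT neurons (Fgf21, the 18th there, was not tested in Perk KO neurons), the Perk KO rise was at the median 25.6% of the WT rise, with a median lower limit of 19.2%, while Eif2ak3 stood at 15.1% of the WT level in controls and 8.84% with TM (highest library 17.8%). Cells with intact Perk were not excluded as the whole cause, since Eif2ak3 RNA need not equal their share. By gene 10 of the 17 targets had a lower limit above these Eif2ak3 shares and the other 7 did not. A candidate explanation is another kinase of eIF2 or another arm of the unfolded protein response, which was not tested.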
